A study of Homo sapiens with 18 samples.

How the data were processed

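The 18 arrays measured RNA of HK-2 cells, an immortalized line of human renal proximal tubular epithelium. Cells had been exposed to CsA or to its vehicle for 12, 24 or 48 h, with 3 biological replicates in each of the 6 groups, all labelled as coming from one laboratory. The labels do not spell out CsA, which is the usual abbreviation of cyclosporin A, and give no dose. Per the labels' protocols, cells were plated a day before treatment, treated near confluence, total RNA was isolated on columns and biotin-labelled cRNA was made for Affymetrix arrays. Samples were grouped by the treatment, time and replicate number in their labels.

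The deposited table held 54675 probe sets on 18 arrays. Per the submitters' processing notes the values were made with GCRMA, with no version given; the authors' deposited values were taken as log2 GCRMA values because of their range. The log base is not written in a label. GCRMA corrects each array's background, normalizes between arrays and summarizes each probe set. Which arrays were normalized together is not given in the sources used here. Array medians lay between 2.856 and 2.923, and between 38.18% and 39.07% of probe sets reached 4 on the log2 scale. The number of arrays limits the precision. GCRMA holds probe sets near background at a common low value, so differences between low values are compressed.

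Probe sets were named through the platform annotation. Of the probe sets, 41091 had 1 gene symbol, 1801 had several, 11721 were unnamed here and 62 were array controls. The symbols were checked by gene identifier against current RefSeq names, which changed 0 symbols, and 54 had no match and kept their own. Tests used probe sets with exactly 1 symbol whose highest group mean was at least 4, and for each gene the probe set with the highest mean over all arrays. Among the genes named, another probe set of XBP1 and of CLU at 12 h and of MRPS25 in the average had the opposite sign. This left 10717 genes. Several listed genes were not analysed here. One listed symbol, DDX58, was read as its current name RIGI.

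Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on all 18 arrays in one model with a term per group, so that the groups shared one estimate of the spread. Benjamini-Hochberg adjustment was used with a threshold of 0.05. Errors printed with a log2 difference are standard errors of that fit, and those printed with a group mean are SDs over 3 arrays. The contrasts were CsA against control at each time, their average, the differences between the times (a moderated F test, and single contrasts), and control arrays over time. Of 37 gene lists fixed for this tissue and compound, 29 had at least 5 tested members and were tested with camera at its preset correlation of 0.01, and again with an estimated correlation. Members of a list were also counted after adjustment over the list alone. The difference between 3-prime and 5-prime control probe sets of ACTB and GAPDH, a sign of RNA quality, was tested with a two-sided exact permutation test over 8000 relabelings within times. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.

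The tests, lists, rule for named genes and all alternatives not said to be added later were fixed before the data were examined. At each time the rule took the 8 largest rises and the 8 largest falls among genes past the threshold whose 3 CsA arrays all lay above or all below the 3 control arrays, the 4 members with the smallest p of each called list in its direction, and 12 preset genes of tubular injury, cyclophilins and stress, of which 11 were tested and 1 was not analysed here. For the average it took the 8 largest changes each way with one sign at all times, for the effect by time the 6 largest differences each way past the F test, and for control arrays the 4 largest each way past theirs. Genes named outside this rule are said to have been chosen after their values were seen.

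The groups share replicate numbers, so it was checked whether the numbers pair the arrays. Over all pairs of groups, the deviations from the group means of arrays with the same number correlated at 0.277 or more across genes, and at 0.546 to 0.942 between CsA and control of one time. Replicate 3 lay apart, so replicates 1 and 2 deviated in part alike from their group means. Positive correlations alone therefore do not tell the pairing of replicate 1 from that of replicate 2. For 18 of 18 arrays the closest array of another group had the same number. Replicate number accounted for 71.5% of the sum of squares within groups, and replicate 3 against the other two for 67.4%. The numbers were therefore taken to pair the arrays, from the data and not from the labels. A fit with the replicate number as a block is given beside a result where it changes the call of a gene or list, or moves a printed count of genes called by more than 1.5 times.

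Alternatives to the level filter, normalization, floor, probe set choice, variance model, array weights, block, arrays in the fit and fold threshold were run, and each array was left out in turn. The tests were tried on simulated data with the means, replicate offsets and noise of the 10717 genes and with added changes at 48 h. The fit without a block recovered 49 of 100 genes changed by 1 and 87 of 100 changed by 2 on the log2 scale, with 0 calls among unchanged genes. With the block it recovered 80 and 97, with 14 of 191 calls among unchanged genes. The simulated noise was independent between genes, and each gene had 1 spread for all arrays. In the data the spread differed between groups. Between control replicates 1 and 2 the SD of the difference over genes was 0.225 at 12 h and 0.494 at 48 h. The simulated rates therefore need not hold for the data.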

Results

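HK-2 cells, a line of human proximal tubular epithelium used to study kidney toxicity, were exposed to CsA or vehicle for 12, 24 or 48 h. Gene expression was measured on 18 arrays, 3 per group. CsA, in common use short for cyclosporin A, is an immunosuppressant that binds cyclophilins and has known effects on the kidney. According to the design text, the study belonged to a set that looked for expression signatures of toxic compounds. Values are GCRMA values on the log2 scale.

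The arrays separated by time and by replicate number. On the first principal component, with 47.1% of the variance, every 48 h array lay above the earlier arrays of its replicate number. On the second, with 32.2%, replicate 3 lay above the other two within each group. Between replicates 1 and 2 of a group, the SD of the difference over genes ranged from 0.225 to 0.494 on the log2 scale. Between replicate 3 and either of the others it ranged from 0.632 to 0.796. LCN2, a secreted protein used as a marker of tubular injury, averaged 11.33 in replicate 3 and 4.14 in the other two. The 3-prime minus 5-prime difference of ACTB, a sign of RNA quality, differed by -0.001 on the log2 scale between CsA and control over the 3 times (two-sided exact permutation test, p = 0.989). That of GAPDH differed by -0.033 (two-sided exact permutation test, p = 0.151). Of the lists for other cell types, fibroblast, endothelial, leukocyte, podocyte and distal nephron markers had 4, 0, 1, 2 and 2 tested members, too few for a set test.

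**Figure D1:**
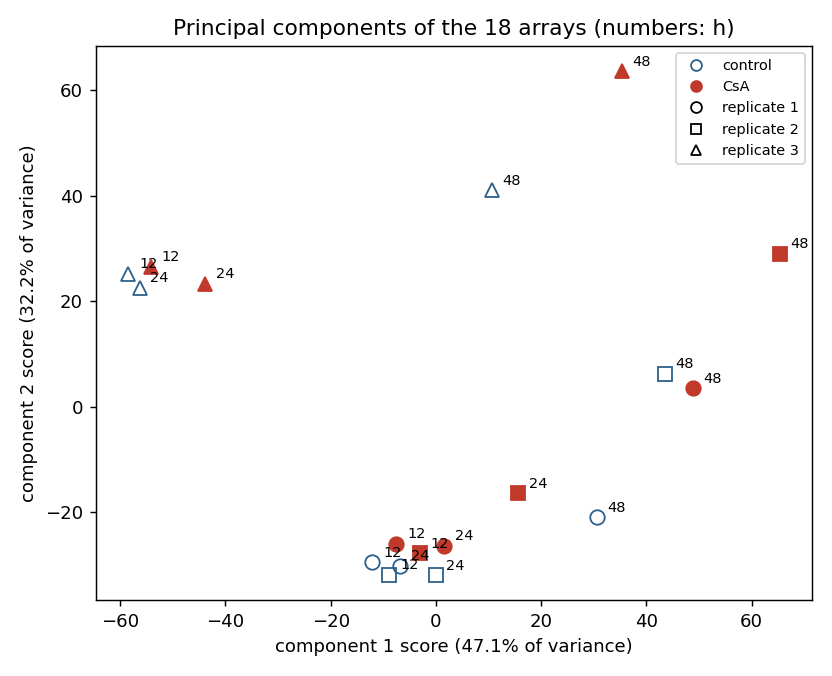
Scores of the 18 arrays on the first and second principal components of the tested genes; the axes give each component's share of the variance (47.1% and 32.2%), filled symbols are CsA, open symbols control, shapes are replicate numbers and labels are hours. Replicate 3 of every group lies above the other two replicates of that group on the vertical axis.

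The first comparison asked what CsA changed at 12 h. Genes for protein folding in the endoplasmic reticulum (ER) were higher with CsA as a group: of 24 tested ER chaperone and ER-associated degradation genes, 23 had a positive difference, with a median of 0.51 on the log2 scale (camera adjusted p = 8.7e-33, adjusted p = 0.0338 with an estimated correlation, and 0.15 with that and the replicate block). Adjusted over the list alone, 4 of them rose, 7 with the replicate block, and 0 did over all genes with or without it. HSPA5, the main ER chaperone, averaged 13.75 ± 0.35 (SD, n = 3) with CsA and 12.68 ± 0.16 in control, a difference of 1.07 ± 0.21 (limma adjusted p = 0.427). DNAJB9, a cochaperone of HSPA5, differed by 0.99 ± 0.29, and SSR1, a subunit of the translocon-associated complex, by 0.61 ± 0.18. XBP1, a transcription factor of the unfolded protein response, differed by 0.61 ± 0.19.

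The coat proteins that carry cargo from ER to Golgi were higher too: 19 of 19 had a positive difference, with a median of 0.21 (camera adjusted p = 4.45e-15, adjusted p = 0.0338 with an estimated correlation, and 0.15 with that and the replicate block), and 1 rose when adjusted over the list alone. SEC24D, a cargo-binding subunit of the COPII coat, differed by 1.06 ± 0.19 (limma adjusted p = 0.276), LMAN1, a cargo receptor, by 0.39 ± 0.20 and SEC31A by 0.31 ± 0.15. PPIB, the cyclophilin of the ER, averaged 12.12 ± 0.29 with CsA and 11.48 ± 0.34 in control. This difference of 0.65 ± 0.27 did not pass the test over all genes with or without the block. PPIA, the abundant cytosolic cyclophilin, differed by -0.06 ± 0.08. No test compared these cyclophilins with each other.

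In 5 other lists called at 12 h, no member passed the test over all genes or over the list alone in the fits on all arrays with or without the block, and the call was lost with an estimated correlation. With the block on the 6 arrays of 12 h alone, an alternative chosen after the data were seen, some passed over the list alone: 11 rose and 1 fell in the ATF4 list, 10 fell in mitosis, 3 rose in cholesterol synthesis and 2 in fatty acid synthesis. In that fit 21 ER chaperones and 6 coat proteins rose over the list alone, and 0 of any of these lists over all genes. The ATF4 list, targets of the integrated stress response, had a median of 0.23 and 21 of 26 genes positive (camera adjusted p = 0.000488, and adjusted p = 0.623 with an estimated correlation). Fatty acid synthesis had a median of 0.23 with 8 of 9 positive (camera adjusted p = 0.00445, and adjusted p = 0.518 with an estimated correlation). Cholesterol synthesis had a median of 0.12 with 14 of 18 positive (camera adjusted p = 0.00598, and adjusted p = 0.518 with an estimated correlation). Mitosis genes were lower, with a median of -0.20 and 25 of 25 negative, CENPF by -0.35 ± 0.26 (camera adjusted p = 0.000488, and adjusted p = 0.928 with an estimated correlation). Cytosolic heat shock proteins were lower by a median of -0.10 with 13 of 14 negative (camera adjusted p = 0.0252, 0.0732 with the replicate block, and adjusted p = 0.863 with an estimated correlation).

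Gene by gene, limma called 0 of 10717 genes at 12 h, with 98 at an unadjusted p under 0.05. It called 0 with the replicate block as well, with 259 at an unadjusted p under 0.05. With the block on the arrays of 12 h alone, an alternative chosen after the data were seen, limma called 0, with 1434. The fits on all arrays share their spread with the 48 h arrays. Between control replicates 1 and 2 the SD of the difference was 0.494 at 48 h and 0.225 at 12 h. The counts of 98 and 259 therefore need not mean that few genes changed at 12 h.

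Some list calls at 12 h were lost with 1 array left out. Without CsA replicate 1, 2 or 3 of 12 h, these were fatty acid synthesis (adjusted p = 0.112) and heat shock proteins (0.112), mitosis (0.216) and heat shock proteins (0.68), and cholesterol synthesis (0.542). Without control replicate 1 or 2 it was cholesterol synthesis (0.0621 and 0.0983). Without control replicate 3 these were fatty acid synthesis (0.113), mitosis (0.128) and heat shock proteins (0.75).

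At 24 h, targets of ATF4, the transcription factor that carries out the integrated stress response, were higher with CsA. Of 26 tested members, 25 had a positive difference, with a median of 0.74 (camera adjusted p = 8.97e-24, adjusted p = 0.0351 with an estimated correlation, and 0.221 with that and the replicate block), and 12 rose when adjusted over the list alone. SLC7A11, the cystine transporter, averaged 8.28 ± 1.58 (SD, n = 3) with CsA and 4.61 ± 0.74 in control, a difference of 3.67 ± 0.57 (limma adjusted p = 0.122, and 0.00691 with the replicate block). STC2, a secreted glycoprotein, differed by 2.18 ± 0.55, DDIT3, a stress-induced transcription factor, by 1.93 ± 0.58, SLC3A2, the heavy chain that pairs with SLC7A11, by 1.16 ± 0.30, and ATF4 itself by 0.82 ± 0.20. STC2 averaged 4.35 ± 1.17 in control, near background, so the size of its difference is not resolved. CsA replicate 2 contributed most: the list's median was 1.36 in replicate pair 2, 0.39 in pair 1 and 0.62 in pair 3.

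ER chaperones were higher at 24 h as well, with a median of 0.44 and 21 of 24 positive; 4 rose when adjusted over the list alone and 8 with the block (camera adjusted p = 2.33e-14, and adjusted p = 0.383 with an estimated correlation). DNAJB9 differed by 1.27 ± 0.29, HERPUD1, a component of ER-associated degradation, by 1.04 ± 0.29 and HSPA5 by 0.91 ± 0.21. The enzymes that charge tRNAs had a median of 0.29 with 12 of 17 positive, CARS1 by 0.77 ± 0.20 and YARS1 by 0.71 ± 0.22, and 1 rose when adjusted over the list alone, 2 with the block (camera adjusted p = 2.04e-06, and adjusted p = 0.383 with an estimated correlation). Positive medians were also those of ER to Golgi coats (0.15, 16 of 19 positive, camera adjusted p = 0.00046, and adjusted p = 0.383 with an estimated correlation), fatty acid synthesis (0.32, 7 of 9, 0.00524, and adjusted p = 0.383 with an estimated correlation) and NRF2 targets (0.11, 11 of 15, 0.0244, and adjusted p = 0.458 with an estimated correlation). Clock genes had a similar shift (0.20, 9 of 13, 0.0244, and adjusted p = 0.433 with an estimated correlation), as did autophagy and lysosome genes (0.16, 14 of 19, 0.027, and adjusted p = 0.547 with an estimated correlation). SLC7A11 is a member of the NRF2 list too. In the clock list BHLHE40, a transcriptional repressor, differed by 0.88 ± 0.16. In the NRF2 and clock lists 1 member each rose when adjusted over the list alone. In the other 3 lists 0 did. With the block it was 2 in the NRF2 list, 1 in the clock list and 3 in fatty acid synthesis.

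Genes of 5 lists were lower with CsA at 24 h. Heat shock proteins of the cytosol had a median of -0.31 with 14 of 14 negative (camera adjusted p = 5.29e-06, and adjusted p = 0.383 with an estimated correlation), DNAJA1 by -0.61 ± 0.19. DNA replication genes had a median of -0.28 with 25 of 25 negative (camera adjusted p = 3.95e-05, and adjusted p = 0.55 with an estimated correlation), CCNE1, the G1/S cyclin, by -0.88 ± 0.39. Mitosis genes had a median of -0.29 with 25 of 25 negative (camera adjusted p = 0.000221, and adjusted p = 0.604 with an estimated correlation). The respiratory chain had a median of -0.07 with 17 of 22 negative (camera adjusted p = 0.00205, and adjusted p = 0.383 with an estimated correlation) and the proteasome a median of -0.14 with 22 of 23 negative (camera adjusted p = 0.00428, and adjusted p = 0.613 with an estimated correlation). No member of these 5 lists fell over all genes or over the list alone without the block. With it 2 heat shock proteins and 1 gene of the respiratory chain fell over the list alone, and on the 6 arrays of 24 h alone with the block, an alternative chosen after the data were seen, 14 mitosis genes and 5 heat shock proteins did.

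Gene by gene, limma called 0 of 10717 genes at 24 h, with 406 at an unadjusted p under 0.05, and with the replicate block it called 1, SLC7A11, with 1009. With the block on the 6 arrays of 24 h alone, chosen after the data were seen, it called 0, with 2086 (SLC7A11 adjusted p = 0.156). In the blocked fit of all times with 1 array left out, the number of genes called at 24 h ranged from 0 to 3. It was 0 without control replicate 1 of 24 h and 3 without CsA replicate 1 of 24 h. List calls were lost without CsA replicate 1 of 24 h (proteasome, adjusted p = 0.158), replicate 2 (proteasome 0.429, DNA replication 0.333, autophagy 0.0709 and clock 0.65) or replicate 3 (NRF2 0.2 and autophagy 0.2). They were also lost without control replicate 1 of 24 h (NRF2 0.0504 and clock 0.121), replicate 2 (NRF2 0.124 and autophagy 0.111) or replicate 3 (proteasome 0.946, autophagy 0.0689 and clock 0.151).

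**Figure D2:**
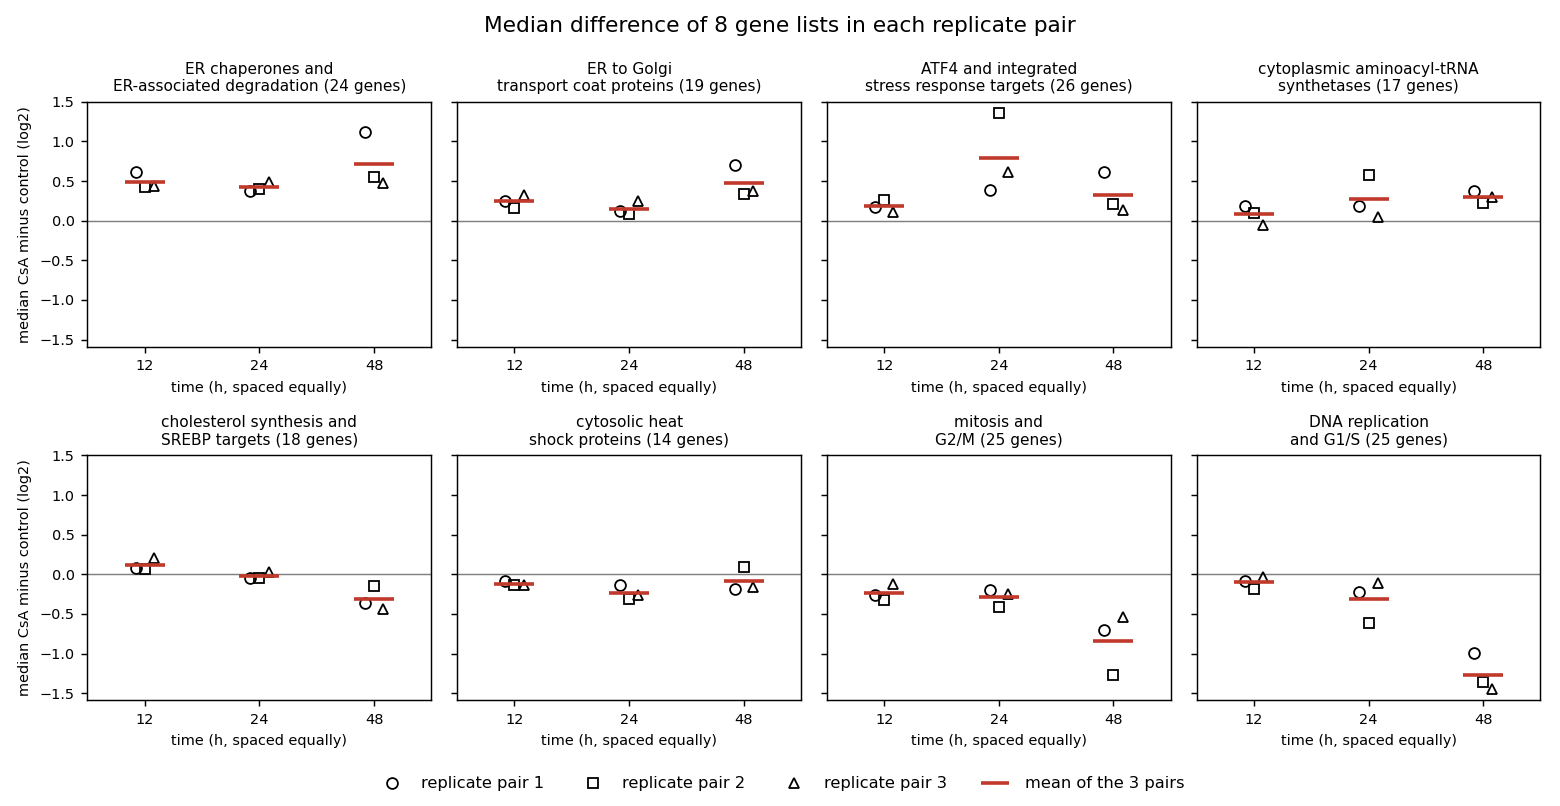
Median log2 difference between CsA and control (vertical axis) over the tested genes of 8 lists in each replicate pair at 12, 24 and 48 h (horizontal axis, spaced equally); symbols are replicate pairs and red bars their mean. The ATF4 list reaches 1.36 in pair 2 at 24 h, and the DNA replication list lies from -1.45 to -0.99 in the 3 pairs at 48 h.

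At 48 h, genes of DNA replication were lower with CsA. Of 25 tested members, 24 had a negative difference, with a median of -1.28 (camera adjusted p = 1.7e-21, and adjusted p = 0.235 with an estimated correlation). Over all genes 2 fell, adjusted over the list alone 23 fell, and with the replicate block 23 fell over all genes. POLE2, a subunit of DNA polymerase epsilon, averaged 6.56 ± 0.92 (SD, n = 3) with CsA and 8.28 ± 0.45 in control, a difference of -1.72 ± 0.34 (limma adjusted p = 0.049). POLA1, the catalytic subunit of polymerase alpha, differed by -1.13 ± 0.19 (limma adjusted p = 0.0318). PCNA, the sliding clamp, differed by -1.27 ± 0.27 (limma adjusted p = 0.0563, and 0.0126 with the replicate block). Among the largest falls past the test without the block, outside the list, were ASF1B, a histone chaperone (-2.43 ± 0.49), HELLS, a chromatin remodeller (-2.19 ± 0.41), and DSCC1, a subunit of a clamp loader (-1.81 ± 0.34). BRI3BP (-2.42 ± 0.48), TNFSF10, the death ligand TRAIL (-1.59 ± 0.28), and EFNB2, a ligand of Eph receptors (-1.43 ± 0.27), fell too. B4GALT6 fell to near background, at 3.88 with CsA, so the size of its fall is not resolved (limma adjusted p = 0.0372, and 0.0465 with values below 4 raised to 4).

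Mitosis genes were lower by a median of -0.75 with 25 of 25 negative, and 11 fell when adjusted over the list alone. With the block 21 fell over the list alone and 14 over all genes (camera adjusted p = 8.5e-11, and adjusted p = 0.379 with an estimated correlation). TOP2A, a topoisomerase, differed by -0.95 ± 0.26 (limma adjusted p = 0.0993, and 0.0287 with the block) and NUSAP1, a spindle protein, by -1.06 ± 0.31 (0.111, and 0.0325 with the block). Cholesterol synthesis had a median of -0.26 with 14 of 18 negative, 4 of which fell when adjusted over the list alone (camera adjusted p = 0.00271, and adjusted p = 0.379 with an estimated correlation). Over all genes 5 fell with the block, among them ACAT2, a thiolase (-1.28 ± 0.37, limma adjusted p = 0.111, and 0.00691 with the block). SQLE, squalene epoxidase, was another (-0.78 ± 0.21, 0.0991, and 0.0336 with the block). Glycolysis had a median of -0.18 with 14 of 15 negative (camera adjusted p = 0.00901, and adjusted p = 0.379 with an estimated correlation). The respiratory chain had one of -0.09 with 16 of 22 negative (camera adjusted p = 0.0388, 0.057 with the replicate block, and adjusted p = 0.379 with an estimated correlation). In both, 0 fell over the list alone without the block, and with it 3 and 4 fell, over the list alone and over all genes. With the block on the 6 arrays of 48 h alone, chosen after the data were seen, 0 fell in either list over the list alone or over all genes.

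ER chaperones remained higher at 48 h, with a median of 0.69 and 24 of 24 positive; 13 rose when adjusted over the list alone, and 9 over all genes with the block (camera adjusted p = 1.24e-11, and adjusted p = 0.379 with an estimated correlation). Replicate pair 1 contributed most: the ER chaperone list's median was 1.12 in pair 1, 0.55 in pair 2 and 0.48 in pair 3. PDIA3, a disulfide isomerase, differed by 0.91 ± 0.26 (limma adjusted p = 0.111, and 0.0235 with the block) and SSR1 by 0.77 ± 0.18 (0.0684, and 0.00814 with the block). SEC61B, a subunit of the translocation channel, differed by 0.69 ± 0.16 (0.0655, and 0.0161 with the block). With the block on the 6 arrays of 48 h alone, chosen after the data were seen, SSR1 did not pass (limma adjusted p = 0.0552). PDIA3 (0.0312) and SEC61B (0.0409) did. Coat proteins had a median of 0.48 with 19 of 19 positive, 14 of which rose when adjusted over the list alone and 6 over all genes with the block (camera adjusted p = 4.02e-11, and adjusted p = 0.19 with an estimated correlation). The coat protein list's median was 0.7 in replicate pair 1, 0.34 in pair 2 and 0.38 in pair 3. COPG1, a COPI subunit, differed by 1.19 ± 0.26 (limma adjusted p = 0.0563, and 0.0112 with the block). The tRNA-charging enzymes had a median of 0.28 with 16 of 17 positive (camera adjusted p = 0.00201, and adjusted p = 0.379 with an estimated correlation). Autophagy and lysosome genes had one of 0.22 with 15 of 19 positive (camera adjusted p = 0.0372, and adjusted p = 0.379 with an estimated correlation). In both lists 0 rose over the list alone without the block. With it 1 tRNA-charging enzyme rose over all genes, and 4 autophagy genes rose and 1 fell over the list alone.

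Among genes that passed the test without the block, the largest rise at 48 h was that of IL20RB, a cytokine receptor subunit, which averaged 6.96 ± 0.31 with CsA and 5.12 ± 0.28 in control (1.84 ± 0.17, limma adjusted p = 0.000126). Next among these came FBXO16, an F-box protein (1.57 ± 0.17), TMEM140 (1.51 ± 0.28) and CFAP69 (1.47 ± 0.23). EML2-AS1, an antisense RNA, averaged 4.01 with CsA and lay near background in control at 2.83, so the size of its difference is not resolved. It passed the test (limma adjusted p = 1.73e-05), but not with values below 4 raised to 4 (0.756). PPIB differed by 1.12 ± 0.27 (limma adjusted p = 0.0693, and 0.0237 with the replicate block) and CDKN1A, a cell cycle inhibitor, by 1.01 ± 0.26 (0.0828, and 0.0152 with the block). The injury marker HAVCR1 differed by -0.68 ± 0.26 (0.214, and 0.0147 with the block), and CCN2 by -1.79 ± 0.98 (0.407, and 0.169 with the block).

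In all, limma called 47 genes at 48 h, 23 higher and 24 lower, and 1153 with the replicate block, 514 higher and 639 lower, which included the 47. Fitted on the 6 arrays of 48 h alone, it called 0 without the block and 824 with it, the latter an alternative chosen after the data were seen. With each array left out the count without the block ranged from 7, without control replicate 1 of 48 h, to 563, without CsA replicate 1 of 48 h. With the block it was 65 without CsA replicate 2 of 48 h, 642 without CsA replicate 3, 134 without control replicate 1 and 1689 without CsA replicate 1. List calls were lost without CsA replicate 1 of 48 h (respiratory chain, adjusted p = 0.0818), replicate 2 (glycolysis 0.227 and respiratory chain 0.139) or replicate 3 (autophagy 0.329). They were also lost without control replicate 1 of 48 h (tRNA-charging enzymes 0.111, respiratory chain 0.0519 and autophagy 0.314), replicate 2 (autophagy 0.103) or replicate 3 (glycolysis 0.113 and respiratory chain 0.196).

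**Figure D3:**
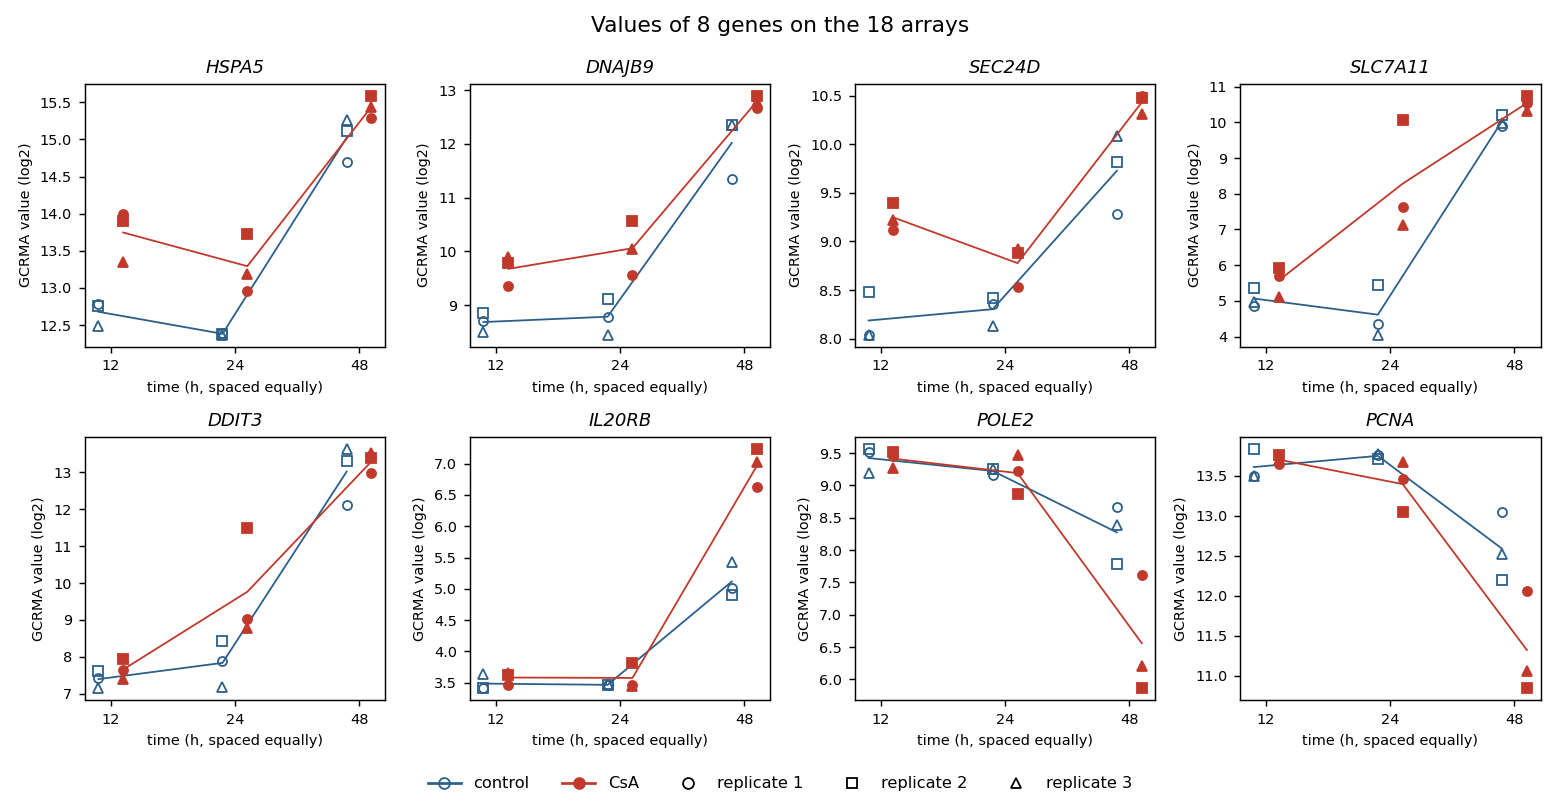
Log2 GCRMA values (vertical axes) of 8 genes on the 18 arrays at 12, 24 and 48 h (horizontal axes, spaced equally); filled red symbols are CsA, open blue symbols control, shapes are replicate numbers and lines join group means. SLC7A11 averaged 8.28 with CsA and 4.61 in control at 24 h, and POLE2 averaged 6.56 and 8.28 at 48 h.

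Averaged over the 3 times, 9 genes passed the test, 8 higher and 1 lower, and 494 with the replicate block, 226 higher and 268 lower. With each array left out the counts ranged from 3, without CsA replicate 2 of 12 h, to 164, without CsA replicate 1 of 48 h. With the block they ranged from 64, without CsA replicate 1 of 12 h, to 976, without CsA replicate 1 of 48 h. Among the 9 were 2 of the ER chaperone list, DNAJB9 (1.01 ± 0.17) and HSPA5 (0.80 ± 0.12), and 1 of the coat protein list, SEC24D (0.75 ± 0.11). With the block 14 and 5 members of these lists rose over all genes. The average of the ER chaperone list had a camera adjusted p of 2.47e-24 (adjusted p = 0.091 with an estimated correlation), and that of the coat protein list one of 1.08e-14 (adjusted p = 0.0739 with an estimated correlation). OSTC, an oligosaccharyltransferase subunit in neither list, rose by 0.62. CREB3L2, a transcription factor of the ER membrane, rose by 1.01 (limma adjusted p = 0.00192), and MRPS25, a mitochondrial ribosomal protein, fell by 0.44 (limma adjusted p = 0.00381). IL20RB and EML2-AS1 were among the 9 as well. With values below 4 raised to 4, the average of EML2-AS1 did not pass (limma adjusted p = 0.916). That of IL20RB was 0.61 with this floor, against 1.84 at 48 h, so it does not show an effect shared by the 3 times. Without replicate 3 of every group, an alternative chosen after the data were seen, 0 genes passed.

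Whether the CsA effect differed between times was tested directly. By the F test 4 genes passed: IL20RB, FBXO16, EML2-AS1 and A1BG, a plasma glycoprotein. The effect at 48 h exceeded that at 12 h by 1.74 ± 0.24 for IL20RB, 1.57 ± 0.24 for FBXO16 and 1.07 ± 0.16 for A1BG. EML2-AS1 lay near background at 12 h, and its 48 minus 12 h difference did not pass with values below 4 raised to 4 (adjusted p = 1). IL20RB and FBXO16 were under 4 in both groups at 12 h as well, and passed the 48 minus 12 h contrast with that floor (limma adjusted p = 0.00318 and 0.0211). With the floor this contrast equals the difference at 48 h, 1.84 for IL20RB and 1.57 for FBXO16. Passing it therefore cannot show that their effect was smaller at 12 h. The 48 minus 12 h contrast called 4 genes, all higher, and 3 with the replicate block, which lost FBXO16 (adjusted p = 0.0607). The effect on the ATF4 list was larger at 24 h than at 12 h, by a median of 0.54 (camera adjusted p = 3.09e-14, and adjusted p = 0.202 with an estimated correlation). At 48 h it was smaller than at 24 h, by -0.56 (camera adjusted p = 1.94e-05, and adjusted p = 0.268 with an estimated correlation). The replicate pairs differed in this: from 24 to 48 h the list's median went from 0.39 to 0.62 in pair 1, from 1.36 to 0.21 in pair 2 and from 0.62 to 0.13 in pair 3. The effect on DNA replication was lower at 48 h than at 12 h, by -1.20 (camera adjusted p = 2.94e-21, and adjusted p = 0.242 with an estimated correlation).

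Control cultures changed over the same period. Between 12 and 48 h, DDIT3 rose by 5.61 ± 0.58, INHBE, an inhibin subunit, by 5.51, ATF3, a stress-induced transcription factor, by 5.15 and SLC7A11 by 4.97 ± 0.57. TXNIP, an inhibitor of thioredoxin (-4.56), and LRRN4 (-2.98) fell. SLN, a regulator of the calcium pump, and TM4SF4 fell to near background, so the sizes of their falls are not resolved. With values below 4 raised to 4, SLN did not pass (adjusted p = 0.0571) and TM4SF4 did (0.00119). The ATF4 list had a median of 1.95, with 20 of 26 members higher over all genes and 23 over the list alone (camera adjusted p = 7.7e-17, and adjusted p = 0.119 with an estimated correlation). ER chaperones had one of 1.46, with 17 of 24 higher and 21 over the list alone (camera adjusted p = 1.06e-16, and adjusted p = 0.276 with an estimated correlation). Mitosis genes were lower by -1.21, with 16 of 25 past the test and 23 over the list alone (camera adjusted p = 1.51e-10, and adjusted p = 0.349 with an estimated correlation). DNA replication genes were lower by -1.03, with 15 of 25 and 23 (camera adjusted p = 3.32e-09, and adjusted p = 0.349 with an estimated correlation). The F test called 1517 genes in controls, and 3594 with the replicate block. Between 12 and 24 h limma called 0, with 131 at an unadjusted p under 0.05, and 0 with the block, with 427.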

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

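The tests of the replicate 3 arrays, of replicate 2 at 24 h, of the course of the control cultures, of RNA quality at 48 h and of array normalization, the splits that exchange pairs between times and the blocked splits of control arrays were chosen only after the result was seen.

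The CsA effect differed between times by the F test in IL20RB (adjusted p = 0.0126), FBXO16 (0.0309, and 0.0622 with the replicate block), EML2-AS1 (0.00165) and A1BG (0.0126). Pair differences were exchanged between times within replicates. By the F test the real count was 4 and the highest other 4, and with the replicate block 3 and 3. The 4 of 36 splits that keep the 3 pairs of 48 h together regroup the same pairs, so for an effect at 48 h alone these splits are too few for a share under 0.05. In the 48 minus 12 h contrast 3 of 100 splits reached the real 4, with 4 as the highest other. That does not exclude chance. In 7 of the 100 splits, the real one among them, the 48 h pairs stay together at a compared time. These regroup the same pairs and called 3 or 4 genes, and all other splits called 0. The share is under 0.05 only because some of these regroupings called 3. With the replicate block 7 of 100 reached the real 3, with 5 as the highest other. These were the 7 splits that keep the 48 h pairs together at a compared time. The share is that of regroupings of the same pairs, so it neither excludes chance nor speaks for it. Exchanging CsA and control within times decides nothing here, since it turns an effect of CsA into a difference between times. By the F test 14 of 100 such splits reached the real 4 (highest other 276) and 20 of 100 the real 3 with the block (184), and in the 48 minus 12 h contrast 13 of 100 reached 4 (5) and 16 of 100 reached 3 with the block (193).

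The effect at 48 h minus that at 12 h differed for 7 lists by camera: DNA replication (adjusted p = 2.94e-21), mitosis (2.46e-06), cholesterol synthesis (5.5e-06), glycolysis (0.0123) and the respiratory chain (0.0403) were lower, and coat proteins (0.00593) and tRNA-charging enzymes (0.0492) higher. With an estimated correlation the smallest of these became adjusted p = 0.242. Outside the named genes, 15 probe sets without exactly 1 gene were called at 48 h, 7 higher and 8 lower, and 192 with the replicate block.

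For single times the 10 splits of the 6 arrays are too few to reach a share under 0.05. At 48 h the real count was 47 and the highest other 182, from a split that set CsA replicate 1 with control replicates 1 and 2, which points to a structure of the arrays other than treatment. Among the splits that part all 3 pairs the highest other was 1, and with the replicate block it was 1 against a real 1153. At 12 and 24 h the real counts were 0 and the highest others 0, and with the block 1 against 0 at 24 h. Of the lists, the real counts were 7, 13 and 9 at 12, 24 and 48 h, and the highest others 7, 10 and 13. Among the splits that part all 3 pairs the highest others were 6, 8 and 8. Chance can be excluded for the average over times, where 1 of 100 splits, the real one, reached its 9 genes, with 4 as the highest other. With the block 1 of 100 reached the real 494, with 2 as the highest other. For control arrays over time, 1 of 100 splits that ignore the replicate number reached the real 1517 genes, with 1470 as the highest other. These splits exchange arrays of different replicate numbers, although replicate number accounted for 71.5% of the sum of squares within groups. They therefore cannot exclude chance. With the block and control arrays exchanged between times within replicates, 1 of 36 reached the real 3594, with 3387 as the highest other. Some of these splits keep the 48 h control arrays together and regroup only 12 and 24 h, between which 0 genes were called with the block. For a change at 48 h alone the blocked splits are therefore too few to decide.

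Replicate 3 stood apart in all 6 groups: 68 genes lay over 1 log2 unit above both other replicates in every group and 124 below. The ACTB 3-prime minus 5-prime difference of replicate 3 was the highest of its group in 0 of 6 groups, which argues against RNA degradation. Of the 8 leukocyte markers analysed here, 1 averaged at least 4 in replicate 3: CD74, at 7.89 against 8.43 in the other two, while PTPRC stood at 2.92 in both and LYZ at 2.86 and 2.85, which argues against leukocyte RNA. The design names no group for replicate number, so no biological explanation was tested, and another passage or state of the cells stays open.

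The ATF4 list at 24 h was higher with CsA. Over the 21 members with a mean of at least 7 the pair medians were 0.42, 1.32 and 0.54, which argues against a change carried by members near background, and the lower of the list medians outside replicate pair 2 was 0.39, which argues against that pair alone. A hypothesis is that the CsA cultures were further along the course that control cultures took by 48 h: over 10219 genes in no list, the effect at 24 h in each pair correlated with the 48 minus 12 h control difference of the other replicates at 0.27, 0.44 and 0.29 (across genes, which are not independent replicates). The correlation was not particular to 24 h: it was 0.19, 0.25 and 0.1 at 12 h, and 0.46, 0.29 and 0.32 at 48 h. After removal of the part that follows that course the ATF4 list medians at 24 h were 0.22, 0.91 and 0.30, against 0.39, 1.36 and 0.62 before. Other handling that moves cultures along the same course, such as cell density, was not tested and stays open.

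DNA replication genes were lower at 48 h in each pair, by -0.99, -1.36 and -1.45. The ACTB 3-prime minus 5-prime difference was higher with CsA in 1 of 3 pairs, by -0.248, 0.391 and -0.004 in pairs 1, 2 and 3. This argues against RNA degradation in the CsA arrays as the source of a fall seen in each pair. The ACTB difference was uneven at 48 h, from 0.714 in control replicate 2 to 1.207 in control replicate 1. What this unevenness did to single genes was not tested. The 1199 genes in no list that were matched by level had pair medians of -0.01, 0.06 and -0.04, the lowest being -0.04. The fall was therefore not shared by genes of that level. Normalization between arrays tends to hold such medians near 0, so they cannot exclude an effect of the normalization itself. After removal of the part that follows the control course the medians were -0.55, -1.20 and -1.05. Whether the CsA cultures were further along that course cannot be told apart from an effect of its own, because no control culture was measured after 48 h.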

How the results depend on the processing

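Fits on replicates 1 and 2 alone, fits on one time with the replicate block, the replicate block without CsA replicate 2 of 24 h, the block with an estimated correlation and the alternatives for RNA quality were chosen only after the data were seen. The 48 minus 12 h contrast was not run on the 6 arrays of one time, since it needs both times. Unless a cause is given, the cause was not tested. Under the replicate block the counts were 1 at 24 h, 1153 at 48 h, 494 for the average and 3594 for control arrays over time; of the counts of genes at 12 h, by the F test and for 48 minus 12 h and of lists at each time it moved none by more than 1.5 times. It ended the list calls of heat shock proteins at 12 h and the respiratory chain at 48 h, and added 5 lists at 48 h. With CsA replicate 2 of 24 h also left out it gave 1, 1008, 169 and 3445, and 2 for 48 minus 12 h. With each array left out of the blocked fit, the average ranged from 64 (without CsA replicate 1 of 12 h) to 976 (without CsA replicate 1 of 48 h), and 48 h from 65 (without CsA replicate 2 of 48 h) to 1689 (without CsA replicate 1 of 48 h).

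Array weights, whose estimate stopped before convergence and which ranged from 0.293 to 7.01, gave 7, 561 and 179 genes at 12, 24 and 48 h, 897 for the average, 10 by the F test, 8 for 48 minus 12 h and 2605 for control arrays. Only the 48 h arrays gave 0 genes at 48 h, or 824 with the block; only the 12 h arrays with the block gave 11 lists. Replicates 1 and 2 alone gave 0 for the average, the F test and 48 minus 12 h, with fewer arrays. The other settings moved 48 h to 73 (trend and robust), 26 (fold of 1 or more on log2), 18 (level of 6), 28 (no level filter), 82 (mean of probe sets) and 106 (probe sets), and the average to 2 (fold), 30 (mean), 14 (median centring), 16 (no filter) and 22 (probe sets). The 48 minus 12 h count moved to 2 (trend and robust) and 7 (probe sets), and control arrays to 554 (fold) and 2586 (probe sets). Median centring gave 24 higher and 22 lower at 48 h, the mean of probe sets 57 and 25, no filter 19 and 9. With an estimated correlation 2, 1 and 0 lists were called at 12, 24 and 48 h, and with that and the block 0, 0 and 0.

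With each array left out without the block, the counts ranged from 0 to 1 at 12 h (1 without control replicate 1 of 48 h), 0 to 1 at 24 h (1 without CsA replicate 2 or 3 of 24 h), 7 to 563 at 48 h, 3 to 164 for the average, 1 to 16 by the F test, 1 to 25 for 48 minus 12 h and 596 to 1631 for control arrays (596 without control replicate 2 of 48 h, 924 without replicate 3). At 48 h, 16 of the 18 moved the count by over 1.5 times: 563 without CsA replicate 1 of 48 h, 266 without control replicate 2, 8 without CsA replicate 2, 7 without control replicate 1, and 12 to 27 without any array of 12 or 24 h. The average was 3 without CsA replicate 2 of 12 h, 5 and 4 without control replicates 1 and 3 of 24 h, 164, 5 and 14 without CsA replicates 1 to 3 of 48 h, and 14, 43 and 15 without control replicates 1 to 3 of 48 h. The F test called 16 without CsA replicate 1 and 1 without control replicate 1 of 48 h. The 48 minus 12 h contrast called 25 without CsA replicate 1 of 48 h, 1 without control replicate 1 of 48 h or any array of 12 h, and 2 without CsA replicate 1 or any control array of 24 h. Lists ranged from 5 to 9 at 12 h, 9 to 14 at 24 h and 8 to 10 at 48 h. ACTB ranged from -0.032 to 0.05 and changed sign in 8 of 18; GAPDH ranged from -0.046 (without control replicate 1 of 48 h, exact permutation test, p = 0.039) to -0.012. Differences that changed sign belonged to HAVCR1 (-0.14 to 0.15) and CLU (-0.33 to 0.63) at 12 h and DDIT3 (-0.17 to 0.59) at 48 h.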

Other observations

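CLIP4, PDK4 and UHRF1, the list values of replicate 3 and the genes named there were chosen only after their values were seen. At 48 h the fit with the replicate block called 5 lists that the fit without it did not. The ATF4 list had a median of 0.32 with 22 of 26 positive (camera adjusted p = 0.0604, 0.043 with the block, and adjusted p = 0.613 with an estimated correlation), and NRF2 targets one of 0.39 with 12 of 15 positive (camera adjusted p = 0.0604, 0.0256 with the block, and adjusted p = 0.379 with an estimated correlation). Metallothioneins and zinc transport genes, which bind and move zinc, were lower in 9 of 9 members by a median of -0.40, 4 of which fell with the block over all genes and 7 over the list alone (camera adjusted p = 0.0964, 0.000216 with the block, and adjusted p = 0.613 with an estimated correlation). NF-kappaB and cytokine genes had a median of -0.80 with 11 of 14 negative, 2 of which fell with the block over all genes (camera adjusted p = 0.15, 0.0205 with the block, and adjusted p = 0.692 with an estimated correlation), and p53 targets one of 0.26 with 14 of 18 positive (camera adjusted p = 0.18, 0.0465 with the block, and adjusted p = 0.379 with an estimated correlation). The p53 list's median was -0.07 in replicate pair 1, 0.45 in pair 2 and 0.23 in pair 3, so pair 1 did not share the rise. PDK4, an inhibitor of pyruvate oxidation, differed by -2.74 ± 0.98 at 48 h (limma adjusted p = 0.191, and 0.0122 with the block), UHRF1, a chromatin protein of S phase, by -2.27 ± 0.52 (0.0655, and 0.00949 with the block) and CLIP4 by 2.08 ± 0.51 (0.07, and 0.0125 with the block). With values below 4 raised to 4 the difference of CLIP4 was 1.84.

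Several lists fixed for this compound passed at no single time with or without the block. The cyclophilin, calcineurin and NFAT list had medians of -0.06, -0.04 and 0.04 at 12, 24 and 48 h (camera adjusted p = 0.669, 0.486 and 0.662), and tubular injury markers medians of 0.06, 0.04 and -0.30 (0.439, 0.4 and 0.219). Matrix genes and targets of TGF-beta had medians of -0.02, 0.06 and -0.06 (0.669, 0.4 and 0.239).

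Replicate 3 differed from the other replicates in single genes and list medians, which were not tested. CLEC4E averaged 11.74 in replicate 3 and 3.07 in the others, IL6 10.66 and 4.24, CCL20 12.74 and 6.89, and MMP1 12.32 and 5.35. CDH1, the epithelial cadherin, averaged 3.80 and 8.19, and FGFR2 4.52 and 8.95. The NF-kappaB list had a median difference of 1.31, with 12 of 14 members higher in replicate 3, and metallothioneins one of 1.06, with 8 of 9 higher. Epithelial junction genes had one of -0.83, with 1 of 17 higher, and YAP and TEAD targets one of -0.57, with 3 of 12 higher.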
